A study of Mus musculus with 9 samples.

How the data were processed

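Total RNA of sorted muscle stem cells from C57BL/6 mice was measured on 9 Illumina bead arrays, 3 each from fetal (embryonic day 16.5), neonatal (7 days after birth) and adult (2 months) mice. Per the labels' protocols, RNA was extracted with the mirVana kit, checked on a Bioanalyser, and amplified and labelled with biotin using the Illumina TotalPrep kit. Per the series' design text, cells were isolated by flow sorting on α7-integrin and CD34. The deposited values are probe intensities on a linear scale; the normalization the authors applied is not given in the sources used here. From the values, the arrays had nearly equal quantiles (5th percentiles 177 to 182), so the table was taken as normalized between arrays, with no further normalization and without the floor of 16 that had been planned for values not yet normalized. The lowest intensities, 118 to 137 per array, lay far above 0, so the changes include background, which compresses those of dim genes. No columns held identical values and every column was used. Values carry no detection p and no read depth. Scan dates or slides were not used here, so batches of that kind were not tested. The hour of collection and the time to sorting were not used either. Their part in the circadian and the immediate early and stress genes reported below was therefore not tested.

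Of 24538 probes, 20211 had 1 gene symbol in the platform annotation, 12 had several and 4315 had none in the table used and were not named. The Entrez identifiers of 20182 probes matched the RefSeq table of the GRCm38.p6 assembly, which changed 0 symbols. For each of 12488 genes the probe with the highest mean over all arrays was used; 4997 genes had more than 1 probe. Other probes of called genes had the same sign in 1088 of 1251 cases for neonatal against fetal, 2962 of 3411 for adult against neonatal and 3703 of 4170 for adult against fetal cells, and 0, 30 and 47 of them were called by limma in the opposite direction. Mki67, Col6a3 and H19, which were to be named whatever their values, were not analysed here.

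Log2 intensities of all 9 arrays were fitted in one linear model with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided), so that the 3 groups shared one estimate of the spread, and the 3 contrasts were neonatal minus fetal, adult minus neonatal and adult minus fetal. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 within a contrast, without a filter on dim genes; "rose" and "fell" refer to called genes. Tested on simulated data with 12488 genes, the procedure made 0 calls for an unchanged neonatal against fetal contrast. For adult against neonatal cells it recovered 61.2% of genes changed 1.5-fold, 97.0% of those changed 2-fold and all 66 changed 4-fold, with 9 false calls, and for adult against fetal cells 53.7%, 98.5% and all 66, with 14 false calls. The simulation drew independent noise for each gene and array and changed 200 genes, in adult arrays only. Correlated genes and the far larger number of calls in the real arrays lie outside that setting, so these rates may not hold there.

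The genes named in the text followed a rule set before the data were examined, as were the gene lists and alternatives. For each contrast these were the 10 largest rises and 10 largest falls among called genes whose groups did not overlap and whose higher mean was at or above the median, leaving out provisional symbols; up to 4 members of each list with the smallest adjusted p; and a fixed set (Itga7, Cd34, Pax7, Myf5, Myod1, Myog, Fn1, Tnc, Vcan, Col6a1, Col6a2, Igf2 and the 3 not analysed here). Where a list had few members that moved in one direction, or the matrix genes that moved in both steps were named, genes outside that rule were named after their values were seen. The 28 lists covered stem cell identity, the Notch pathway, myogenic regulators and fusion, contractile genes, the cell cycle, collagens, matrix glycoproteins, basement membrane, proteoglycans, matrix remodelling enzymes, matrix receptors, the Wnt pathway, the TGF-beta and BMP pathway, fetal growth and imprinted genes, glycolysis, oxidative phosphorylation, fatty acid and lipid use, ribosomal proteins, interferon and antigen presentation, immediate early and stress genes, circadian output, chromatin and DNA methylation, and markers of fibroadipogenic, endothelial, immune, erythroid, mural and smooth muscle, and Schwann and neural cells. Each list was tested in each contrast with camera of limma at a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over all 84 tests. Camera called 32 of them, 21 up and 11 down. None of these 32 calls held with the correlation estimated from the arrays for each list, so that adjusted p is given beside each. Changes of members were also counted adjusted over the list alone.

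Replicate numbers 1 to 3 recur in each age group of the labels. Whether they pair the arrays was checked before the fits were compared, by the correlation across genes of same-numbered arrays' deviations from their group means. These were 0.107 to 0.294 for all 3 neonatal and fetal pairs, above the bound of 0.1. Pairs of different numbers gave -0.264 to 0.234. By that bound the numbers were taken to pair neonatal with fetal arrays. The 0.234, of neonatal replicate 2 with fetal replicate 3, lay above the same-numbered pairs 2 (0.122) and 3 (0.107). The check therefore does not establish the pairing, which comes from the data and not from a statement in the labels. Other alternatives were another between-array scaling, filters on dim genes, other rules for probes, other variance models, thresholds, only the 6 arrays compared, leaving out each array, and, added after the data were seen, normexp background correction with an offset of 16 and leaving out both first replicates of fetal and neonatal cells. Splits of the arrays were refitted in the same way.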

Results

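Muscle stem cells, the cells that sit along skeletal muscle fibres and rebuild muscle after injury, were profiled at 3 ages of C57BL/6 mice on Illumina bead arrays. Fetal cells came from embryonic day 16.5, neonatal cells from 7 days after birth and adult cells from 2 months of age, with 3 arrays per age and 9 arrays in all. The cells had been isolated by flow sorting on the laminin receptor subunit α7-integrin and on CD34, and the title of the series concerns remodelling of the extracellular matrix and regenerative capacity over development. Each array reported 24538 probes, of which 12488 genes were tested. The lowest intensity per array lay between 118 and 137 and the 5th percentile between 177 and 182. Array data carry no read depth, so the number of arrays limited the precision. Nothing in the labels said that replicates came from separate animals, so the p-values measure the spread between these samples, which may be technical. Values are means of log2 intensity ± SD over 3 arrays, changes are log2 fold changes with their SE, and adjusted p-values come from limma unless another test is named.

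Arrays grouped by age. Across genes, which are not independent replicates, the Pearson correlation of log2 intensities was 0.987 to 0.994 between fetal arrays, 0.983 to 0.994 between neonatal arrays and 0.979 to 0.987 between adult arrays. It was 0.963 to 0.972 between fetal and neonatal arrays, 0.897 to 0.957 between neonatal and adult arrays and 0.872 to 0.927 between fetal and adult arrays. The first principal component held 70.3% of the variance and placed the fetal arrays between -40.2 and -29.1, the neonatal arrays between -21.3 and -8.78 and the adult arrays between 39.8 and 60.7. Adult replicate 3, at 39.8, lay nearest to the neonatal arrays. The third component, with 4.09% of the variance, set apart neonatal replicate 1 at 21.6 and, less far, fetal replicate 1 from the other arrays, which lay between -9.83 and -0.53.

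**Figure D1:**
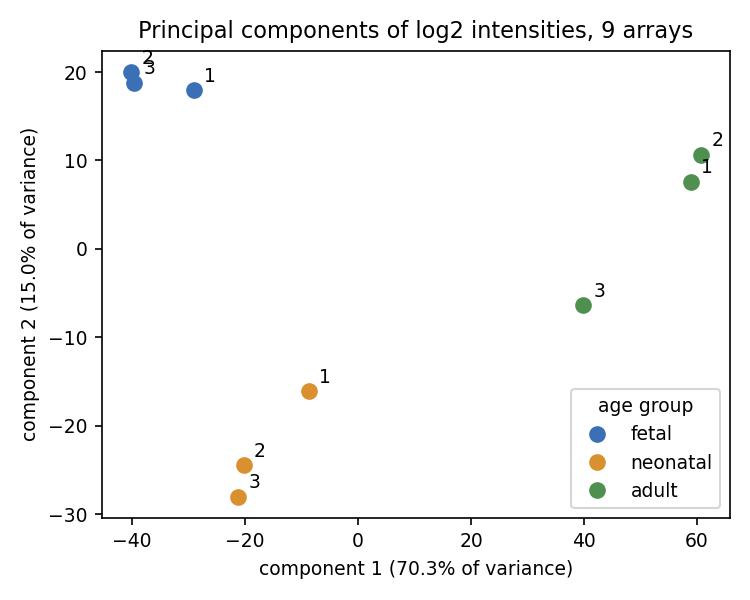
Scores of the 9 arrays on principal component 1 (x axis, 70.3% of the variance) and component 2 (y axis) of log2 intensities; each point is 1 array, colours are ages and numbers are replicates. The adult arrays lie between 39.8 and 60.7 on component 1 and all fetal and neonatal arrays lie below 0.

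The genes of the sort and of myogenic identity had different courses. Itga7, which encodes α7-integrin, measured 12.15 ± 0.22 in fetal, 12.61 ± 0.28 in neonatal and 13.01 ± 0.26 in adult cells (SD, n = 3 each), and rose from fetal to adult by 0.87 (SE 0.18, limma adjusted p = 0.00194). Cd34 measured 9.11 ± 0.10, 9.16 ± 0.28 and 9.44 ± 0.52 and was not called in any comparison (adult against fetal 0.33, SE 0.23, limma adjusted p = 0.252). Pax7, the transcription factor that marks muscle stem cells, measured 8.48 in fetal and 8.50 in neonatal cells (change 0.01, SE 0.16, limma adjusted p = 0.972), and rose in adult cells by 1.13 against neonatal cells (SE 0.16, limma adjusted p = 0.000196). Myod1, the myogenic determination factor, rose at the first step by 1.16 (SE 0.13, limma adjusted p = 0.000146), and its adult level of 12.04 ± 0.18 was not called different from the neonatal level of 12.16 ± 0.14. Myf5 measured 7.77, 7.48 and 7.74 in the 3 groups, close to the low end of the arrays, and was not called in any comparison. Myog, a factor of terminal differentiation, fell by 1.56 from neonatal to adult cells (SE 0.49, limma adjusted p = 0.0266), with adult replicate 3 at 12.29 beside 10.41 and 9.86 in the other adult arrays. That call was lost without neonatal replicate 2 (adjusted p = 0.0753), neonatal replicate 3 (0.108), adult replicate 1 (0.0990) or adult replicate 2 (0.115).

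The first comparison asked what differed between fetal and neonatal stem cells. Transcripts of red blood cells were among the largest rises. The alpha globin gene Hba-a1 went from 9.71 ± 1.38 in fetal to 15.31 ± 0.72 in neonatal cells, a log2 change of 5.60 (SE 0.55, limma adjusted p = 5.64e-05). That size may be a lower bound, since 15.31 lies near the highest values of these arrays. Slc4a1, the red cell anion exchanger, rose by 3.40 (SE 0.39, limma adjusted p = 0.000177). Its fetal level of 7.66 lay near the low end of these arrays, so that size is a lower bound. Among genes outside that list, the calcium pump gene Atp2a3 rose by 4.22 (SE 0.34), the hormone gene Erfe by 3.60 (SE 0.34), the lipase inhibitor gene Angptl4 by 3.36 (SE 0.33) and the receptor kinase gene Ret by 3.13 (SE 0.30). The largest falls were in Igf2bp1, an RNA-binding protein of fetal tissues, which fell by 3.06 (SE 0.13, limma adjusted p = 3.38e-07), and in Hif3a, a member of the hypoxia factor family, which fell by 3.04 (SE 0.18). The neonatal level of Hif3a, 7.57, lay near the low end of these arrays, so its size is a lower bound. Tnni2, the fast troponin I of the contractile apparatus, fell by 2.72 (SE 0.22). Igfbp2, a binding protein of insulin-like growth factors, fell by 2.39 (SE 0.15). In all, 1590 of 12488 genes were called by limma, 751 higher and 839 lower in neonatal cells, and 389 of them changed by at least 2-fold. For 4079 genes (32.7%) the groups did not overlap, where chance gives 10%. The number of calls depended on which array was left out. It was 881 without fetal replicate 2, 927 without fetal replicate 3 and 899 without neonatal replicate 3. It was 1081 without neonatal replicate 2, but 1425 without fetal replicate 1 and 1510 without neonatal replicate 1. The number of falls alone was 538 without neonatal replicate 2.

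Matrix genes moved in both directions between fetal and neonatal cells. Tnc, which encodes the matrix glycoprotein tenascin C, fell from 13.66 ± 0.05 to 12.33 ± 0.28 (change -1.33, SE 0.19, adjusted p = 0.000774). Vcan, encoding the large proteoglycan versican, was lower too (limma adjusted p = 2.81e-05), at 10.51 ± 0.10 in fetal and 9.01 ± 0.21 in neonatal cells. Has2, a hyaluronan synthase, fell by 2.07 (SE 0.20, adjusted p = 5.09e-05). Fn1, encoding fibronectin, was not called (-0.80, SE 0.29, adjusted p = 0.100), with neonatal replicate 1 at 12.88 beside 11.54 and 11.63 in the other neonatal arrays, and Col6a1 and Col6a2, collagen VI chains, were not called (-0.01, SE 0.13, and -0.61, SE 0.24). Of 42 matrix glycoprotein genes 12 fell, 6 rose and 24 were not called, and of 26 proteoglycan genes 6 fell and 1 rose. Of 32 collagen genes 3 fell, among them Col18a1 (-1.24, SE 0.15), and 3 rose, among them Col15a1 (0.71, SE 0.18). The Col15a1 call was lost without fetal replicate 2 (adjusted p = 0.100), fetal replicate 3 (0.0863), neonatal replicate 2 (0.0536) or neonatal replicate 3 (0.0952). Of 18 basement membrane genes 5 rose, among them the perlecan gene Hspg2 (0.82, SE 0.14), and 3 fell, among them the laminin gene Lama5 (adjusted p = 0.00111). Of 44 remodelling enzyme genes 8 rose, including the gelatinase gene Mmp2 (1.28, SE 0.12) and the protease gene Htra1 (1.42, SE 0.16), and 5 fell. Of 27 matrix receptor genes 6 fell, including the hyaluronan receptor gene Cd44 (-1.46, SE 0.23), and 2 rose, including the dystroglycan gene Dag1 (0.83, SE 0.17). Adjusted over the list alone, 8 glycoprotein genes rose and 14 fell, 1 proteoglycan gene rose and 9 fell, 3 collagen genes rose and 3 fell, 5 basement membrane genes rose and 5 fell, 9 enzyme genes rose and 8 fell, and 6 receptor genes rose and 10 fell.

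None of the 6 matrix lists was shifted as a set between fetal and neonatal cells by camera, the gene set test of limma, with adjusted p of 0.591 for collagens, 0.540 for glycoproteins, 0.767 for basement membrane, 0.0912 for proteoglycans, 0.963 for enzymes and 0.384 for receptors. For the basement membrane list the median change was 0.07 and the mean -0.01, and for the enzyme list the median was -0.09 while the test pointed up. Without neonatal replicate 1 the collagen (adjusted p = 0.00605), glycoprotein (0.0243) and proteoglycan (0.00285) lists were called lower in neonatal cells, and without fetal replicate 2 the proteoglycan list was (0.0408). On all arrays these lists had an adjusted p = 0.912, 0.912 and 0.668 with an estimated correlation. Markers of other cell types differed in the same arrays: the list of fibroadipogenic markers, genes of connective tissue cells, had a median log2 intensity of 10.36 in neonatal replicate 1 against 8.86 and 8.89 in neonatal replicates 2 and 3, and 10.04 to 10.51 in fetal arrays. Of its 17 members 5 fell and 2 rose between fetal and neonatal cells (the same counts adjusted over the list alone; adjusted p = 0.219), with Meox1 at -1.19 (SE 0.16), and it was called lower without neonatal replicate 1 (adjusted p = 0.00109; on all arrays adjusted p = 0.772 with an estimated correlation). Of 16 mural and smooth muscle markers 3 fell and 0 rose by limma (6 fell and 1 rose adjusted over the list alone; adjusted p = 0.0912), and that list too was called lower without neonatal replicate 1 (adjusted p = 0.00183; on all arrays adjusted p = 0.661 with an estimated correlation).

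**Figure D2:**
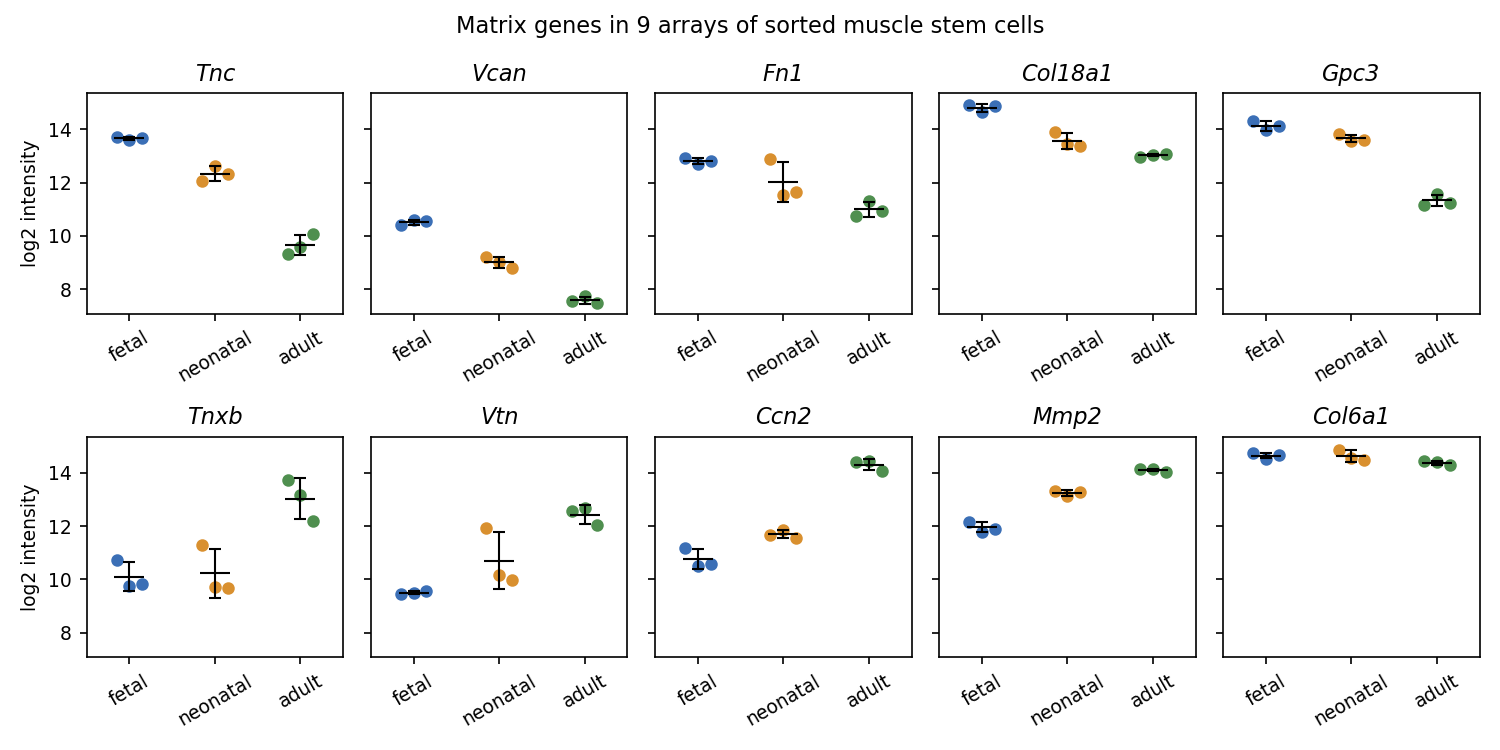
Log2 intensity (y axis) of 10 matrix and matrix-related genes in fetal, neonatal and adult cells; each point is 1 array and bars give mean ± SD of 3 arrays. Tnc lies at 13.66 in fetal, 12.33 in neonatal and 9.67 in adult cells, Ccn2 at 10.77, 11.70 and 14.31, and Col6a1 at 14.64, 14.63 and 14.37.

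Of 22 fetal growth and imprinted genes 8 fell and 0 rose by limma (10 fell and 0 rose adjusted over the list alone), including Nnat (-1.44, SE 0.12), Igf2bp3 (-1.32, SE 0.12) and the growth suppressor gene Ndn (-1.13, SE 0.11). The list was shifted down (camera adjusted p = 1.84e-06; adjusted p = 0.0577 with an estimated correlation). Igf2, the fetal growth factor, measured 15.75 ± 0.14 and 15.71 ± 0.07, near the highest values of these arrays, where a change can go unmeasured. Of 45 cell cycle genes 3 fell (Ccne1, Gins2 and Mcm6), 0 rose and 0 were called by limma adjusted over the list alone. Each of the 3 calls was lost without fetal replicate 2 or 3 or without any 1 of the neonatal replicates, and those of Gins2 and Mcm6 also without fetal replicate 1. The adjusted p then lay between 0.0644 and 0.133 for Ccne1, between 0.0526 and 0.137 for Gins2 and between 0.0855 and 0.142 for Mcm6. The list was called lower with a median of -0.24 (camera adjusted p = 0.0297; adjusted p = 0.778 with an estimated correlation), and not without fetal replicate 2 (0.114), fetal replicate 3 (0.0675) or neonatal replicate 1 (0.110). It was also not called when genes under the median intensity were left out (0.0973). Fry, which tests a list against no change and not against other genes, did not call it either (0.529). Of 28 chromatin and DNA methylation genes 3 fell and 0 rose by limma, with the same counts adjusted over the list alone (camera adjusted p = 0.101).

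Of 37 interferon and antigen presentation genes 12 rose and 0 fell by limma (14 rose and 0 fell adjusted over the list alone), with the class I gene H2-D1 up by 2.11 (SE 0.20) and the peptide transporter gene Tap2 by 1.13 (SE 0.18). The interferon list was shifted up (camera adjusted p = 6.29e-07; adjusted p = 0.340 with an estimated correlation). Of 34 immediate early and stress genes 14 rose and 2, Klf6 and Cebpd, fell (17 and 2 adjusted over the list alone) (camera adjusted p = 1.64e-06; adjusted p = 0.350 with an estimated correlation). Ier3 rose by 1.46 (SE 0.22) and the DNA damage response gene Gadd45a by 1.35 (SE 0.21). Of 14 circadian genes 7 rose and 1 fell (9 and 2 adjusted over the list alone) (camera adjusted p = 4.99e-05; adjusted p = 0.295 with an estimated correlation). The clock output gene Dbp rose by 2.48 (SE 0.18) and the clock repressor gene Nr1d1 by 1.98 (SE 0.12). Of 10 erythroid markers 5 rose and 0 fell by limma (6 rose and 0 fell adjusted over the list alone), and this list was shifted up beside those groups (camera adjusted p = 2.30e-07; adjusted p = 0.274 with an estimated correlation). Hba-a1 stood at 11.27 in fetal replicate 2 against 8.62 and 9.24 in the other fetal arrays. Near-identical globin copies such as Hbb-bs and Hbb-bt, up by 5.54 and 5.57, cannot be assumed to be told apart by the probes. Those sizes may be lower bounds, since the neonatal levels lay near the highest values of these arrays.

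Of 17 myogenic regulator and fusion genes 4 rose and 1 fell (5 and 2 adjusted over the list alone), including the acetylcholine receptor subunit gene Chrna1 (1.89, SE 0.15) and its organising kinase gene Musk (0.83, SE 0.14), while Igfbp5 fell by 0.78 (SE 0.14). The myogenic list was shifted up (camera adjusted p = 0.00566; adjusted p = 0.274 with an estimated correlation). Of 19 stem cell identity genes 4 rose and 1 fell (6 and 1 adjusted over the list alone), with the calcitonin receptor gene Calcr, a marker of quiescent muscle stem cells, up by 1.39 (SE 0.22). That list was shifted up (camera adjusted p = 0.0139; adjusted p = 0.326 with an estimated correlation), and not without fetal replicate 2 (0.0624). Of 29 contractile genes 5 rose and 4 fell (6 and 6 adjusted over the list alone; camera adjusted p = 0.962). Of 19 endothelial markers 2 rose and 3 fell (3 and 3 adjusted over the list alone; camera adjusted p = 0.549). The endothelial list was called lower, with a median of -0.78, when genes under the median intensity were left out (adjusted p = 0.0330), against a median of 0.09 over all its genes (adjusted p = 0.912 with an estimated correlation). Of 11 immune markers 1 rose and 0 fell by limma (0 and 0 adjusted over the list alone; adjusted p = 0.233), and of 10 Schwann and neural markers 0 rose and 1, Ngfr, fell (the same adjusted over the list alone; adjusted p = 0.771). Mbp, a myelin gene, measured 11.12 in neonatal replicate 1 and 8.48 and 8.75 in the other neonatal arrays.

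The second comparison asked what differed between neonatal and adult stem cells. Every one of the 45 measured cell cycle genes fell, with a median log2 change of -2.31. Cdk1, the kinase that drives mitosis, fell by 3.36 (SE 0.44, adjusted p = 0.000131), and the DNA topoisomerase gene Top2a fell by 3.32 (SE 0.51, adjusted p = 0.000360). The S phase genes Ccne2 and Gins2 fell by 2.59 (SE 0.21) and 2.02 (SE 0.15). The largest rises were in single genes of different kinds. Hsd11b1, which regenerates active glucocorticoid, rose by 4.51 (SE 0.27, adjusted p = 8.99e-07), the steroid sulfate transporter gene Slc10a6 by 4.34 (SE 0.33), the smooth muscle myosin gene Myh11 by 4.31 (SE 0.29) and the myelin gene Mbp by 4.19 (SE 0.52). Gal, which encodes the neuropeptide galanin, rose by 4.07 (SE 0.41), to an adult level near the highest values of these arrays, so that size may be a lower bound. Limma called 4718 genes, 2376 higher and 2342 lower in adult cells, of which 1306 changed by at least 2-fold, and the groups did not overlap for 5946 genes (47.6%, where chance gives 10%). The cell cycle list was shifted down by camera (adjusted p = 4.02e-23; adjusted p = 0.306 with an estimated correlation), and all 45 members were also called adjusted over the list alone. Its median log2 intensity was 11.63 to 11.79 in neonatal arrays, 8.63 and 8.46 in adult replicates 1 and 2, and 10.13 in adult replicate 3.

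Between neonatal and adult cells, of 28 chromatin and DNA methylation genes 20 fell and 2 rose (21 and 3 adjusted over the list alone), including the maintenance methyltransferase gene Dnmt1 (-1.87, SE 0.13) and its partner gene Uhrf1 (-2.98, SE 0.33). The chromatin list was shifted down (camera adjusted p = 1.83e-05, and 0.226 with an estimated correlation). Uhrf1 belongs to the cell cycle list as well, and whether the chromatin list fell apart from the cell cycle genes was not tested. Of 22 fetal growth and imprinted genes 11 fell and 1, Dcn, rose (the same counts adjusted over the list alone), with the RNA-binding protein gene Igf2bp3 down to 7.60 ± 0.14 (change -3.60, SE 0.12, adjusted p = 3.87e-08) (camera adjusted p = 7.12e-05; adjusted p = 0.0900 with an estimated correlation). Dlk1 and Igf2 changed by -3.35 (SE 0.18) and -1.28 (SE 0.13), sizes that may be lower bounds, since their neonatal levels lay near the highest values of these arrays. The size for Igf2bp3 is a lower bound, since its adult level lay near the low end. Of 57 oxidative phosphorylation genes 28 fell and 2, Uqcrq and Cox7a1, rose (33 and 2 adjusted over the list alone), with a median of -0.44 (camera adjusted p = 1.64e-06; adjusted p = 0.409 with an estimated correlation). Xist, the RNA of the inactive X chromosome, had the largest measured fall, from 11.71 ± 1.03 to 7.30 ± 0.18 (change -4.41, SE 0.37, limma adjusted p = 8.89e-06). Its adult level lay near the low end of these arrays, so the size is a lower bound and its rank is open.

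Tenascin C and versican transcripts fell further in adult cells, while some other matrix genes rose. Markers of vessels and nerves rose in the same arrays, and whether cells other than stem cells contributed to the matrix changes was not tested. Tnc fell by 2.66 (SE 0.19, adjusted p = 2.89e-06) and Vcan by 1.41 (SE 0.13, adjusted p = 1.56e-05). Gpc3, encoding the proteoglycan glypican 3, fell by 2.33 (SE 0.15). Fn1 fell by 1.02 (SE 0.29, adjusted p = 0.0164), a call lost without adult replicate 1 (adjusted p = 0.0643), and Col6a1 and Col6a2 were not called (adjusted p = 0.133 and 0.0629). Of 42 matrix glycoprotein genes 19 rose and 7 fell (20 and 7 adjusted over the list alone), with Ccn2, a matricellular growth factor gene, up by 2.60 (SE 0.18) and Sparcl1 by 1.69 (SE 0.15). Of 26 proteoglycan genes 8 rose and 4 fell (the same adjusted over the list alone), among them Prelp (2.16, SE 0.28). Of 32 collagen genes 11 fell and 4 rose (13 and 5 adjusted over the list alone), including the basement membrane chain gene Col4a2 (-1.22, SE 0.19) and Col15a1 (-1.51, SE 0.18). Of 18 basement membrane genes 8 fell and 2 rose (9 and 2 adjusted over the list alone): the laminin gene Lamb1 fell by 1.51 (SE 0.16), and Lamb2 and Lamc3 rose by 1.83 (SE 0.22) and 2.85 (SE 0.22). Of 44 remodelling enzyme genes 17 rose and 5 fell (18 and 5 adjusted over the list alone), including the heparan sulfatase gene Sulf1 (3.48, SE 0.22) and the protease inhibitor gene Timp3 (1.56, SE 0.19). Of 27 matrix receptor genes 7 rose and 2 fell (the same adjusted over the list alone), with the integrin gene Itgav up by 1.30 (SE 0.19).

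Among the matrix lists the remodelling enzymes were shifted up as a set between neonatal and adult cells (camera adjusted p = 0.00768; adjusted p = 0.647 with an estimated correlation). The others were not called, with camera adjusted p of 0.0538 for glycoproteins, 0.172 for collagens, 0.0912 for basement membrane, 0.399 for proteoglycans and 0.193 for receptors. The glycoprotein list crossed the threshold with the replicate number as a block (adjusted p = 0.0261), with quantile normalization (0.0493), without neonatal replicate 1 (0.00250), without adult replicate 1 (0.0234) and without fetal replicate 1 or 2 (0.0431 and 0.0498). On all arrays it had an adjusted p = 0.668 with an estimated correlation. Without neonatal replicate 3 the collagen and basement membrane lists were called lower (both 0.0445), and the collagen list was also called lower, with a median of -0.58, when genes under the median intensity were left out (0.00717). With all arrays and genes these lists had an adjusted p = 0.772 and 0.661 with an estimated correlation.

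Markers of vessels and nerves moved beside these groups. Of 19 endothelial markers 14 rose and 0 fell by limma (17 and 0 adjusted over the list alone) (camera adjusted p = 2.30e-07; adjusted p = 0.350 with an estimated correlation). The junction gene Esam rose by 3.08 (SE 0.34). Of 16 mural and smooth muscle markers 12 rose and 0 fell by limma (13 and 0 adjusted over the list alone), including Mylk, a myosin kinase gene (3.41, SE 0.34) (camera adjusted p = 1.64e-06; adjusted p = 0.295 with an estimated correlation). Of 10 Schwann and neural markers 5 rose and 0 fell by limma (the same adjusted over the list alone), including Sox10, a factor of the Schwann lineage, which went from 7.58 ± 0.25 to 10.50 ± 0.32 (camera adjusted p = 0.0149; adjusted p = 0.306 with an estimated correlation). Of 10 erythroid markers 5 fell and 0 rose by limma (the same adjusted over the list alone), with Slc4a1 down to 7.80 ± 0.14 (camera adjusted p = 0.0151; adjusted p = 0.451 with an estimated correlation). Hba-a1 measured 13.71 ± 0.39 in adult cells. Of 11 immune markers 4 rose and 0 fell by limma (the same adjusted over the list alone, camera adjusted p = 0.213). The immune list's median lay between 7.53 and 7.86 in all arrays, near the low end. In fetal arrays 0 of its members lay at or above the median of all genes, so it could show little about immune cells. Of 17 fibroadipogenic markers 4 rose and 1 fell (the same adjusted over the list alone, camera adjusted p = 0.284). The fibroadipogenic list was called higher without neonatal replicate 1 (adjusted p = 0.00929; on all arrays adjusted p = 0.790 with an estimated correlation). When genes under the median intensity were left out, the erythroid (adjusted p = 0.239) and Schwann (0.124) lists were no longer called.

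Among the other lists in adult against neonatal cells, of 37 interferon and antigen presentation genes 26 rose and 1, Rsad2, fell (the same adjusted over the list alone) (camera adjusted p = 8.52e-09; adjusted p = 0.306 with an estimated correlation). The immunoproteasome gene Psmb8 rose by 1.47 (SE 0.11) and the class I gene H2-T23 by 2.27 (SE 0.23). Of 34 immediate early and stress genes 29 rose and 1, Cebpd, fell (31 and 1 adjusted over the list alone) (camera adjusted p = 6.60e-11; adjusted p = 0.295 with an estimated correlation). Atf3 rose by 1.52 (SE 0.14) and the metal-binding gene Mt2 by 2.03 (SE 0.21). Of 14 circadian genes 9 rose and 0 fell by limma (the same adjusted over the list alone) (camera adjusted p = 0.000115; adjusted p = 0.295 with an estimated correlation). Per1 rose by 1.89 (SE 0.24). Of 19 stem cell identity genes 5 rose and 1 fell (the same adjusted over the list alone; camera adjusted p = 0.241). Of 17 myogenic regulator and fusion genes 4 rose and 4 fell (5 and 6 adjusted over the list alone; camera adjusted p = 0.996), including the fetal acetylcholine receptor subunit gene Chrng, which fell by 2.84 (SE 0.49); the median of that list was -0.12 while the test pointed up. Of 29 contractile genes 6 rose and 7 fell (6 and 9 adjusted over the list alone; camera adjusted p = 0.663), with the perinatal myosin gene Myh8 down by a change of -2.79 (SE 0.37) and the fast fibre gene Actn3 up by 2.44 (SE 0.14).

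The third comparison set adult against fetal cells, the ends of the series. The RNA-binding protein genes Igf2bp3 and Igf2bp1 changed by -4.92 (SE 0.12, limma adjusted p = 6.99e-10) and -4.14 (SE 0.13, limma adjusted p = 3.61e-09). Their adult levels lay near the low end of these arrays, so both sizes are lower bounds. Tnc was among the 10 largest falls of all genes, from 13.66 ± 0.05 to 9.67 ± 0.38 (SE of the change 0.19, adjusted p = 5.42e-08). The largest measured rises were in Gal (6.19, SE 0.41), in Erfe (5.99, SE 0.34), in Hsd11b1 (5.87, SE 0.27) and in Mbp (5.75, SE 0.52), and Gpx3, a secreted glutathione peroxidase gene, rose by 5.26 (SE 0.13, adjusted p = 6.99e-10). The adult levels of Gal (15.01), Erfe (15.26) and Gpx3 (15.70) lay near the highest values of these arrays, so their sizes may be lower bounds and their order is open. Igfbp6 rose by 4.59 (SE 0.59) and the integrin gene Itgb4 by 4.59 (SE 0.58). Limma called 5654 genes, 2733 higher and 2921 lower in adult cells, with 1812 changed by at least 2-fold, and the groups did not overlap for 6807 genes (54.5%, where chance gives 10%). The neonatal mean lay between the fetal and adult means for 4115 of the 5654 genes (72.8%), was nearer to the fetal mean for 2906 of those, and the median gene had completed 26.4% of its change by the neonatal stage.

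Of the 111 genes of the collagen, glycoprotein, basement membrane and proteoglycan lists together, 34 rose and 33 fell. A part played by cells other than stem cells was not tested here either. Vcan fell by 2.92 (SE 0.13, adjusted p = 4.13e-08), Fn1 by 1.81 (SE 0.29, adjusted p = 0.000327), the microfibril gene Mfap2 by 3.18 (SE 0.27) and Gpc3 by 2.80 (SE 0.15). Col6a2 fell by 1.23 (SE 0.24, adjusted p = 0.00141), while Col6a1 was not called (-0.27, SE 0.13, adjusted p = 0.111). Ccn2 rose by 3.54 (SE 0.18), Prelp by 3.35 (SE 0.28) and the glycoprotein gene Reln by 2.17 (SE 0.17). Of 42 glycoprotein genes 18 rose and 11 fell (19 and 12 adjusted over the list alone; camera adjusted p = 0.193), and of 26 proteoglycan genes 8 rose and 6 fell (the same adjusted over the list alone; 0.883). Of 32 collagen genes 6 rose and 13 fell (the same adjusted over the list alone; 0.173), and of 18 basement membrane genes 3 rose and 7 fell (3 and 8 adjusted over the list alone; 0.288). The collagen list was called lower, with a median of -1.01, when genes under the median intensity were left out (adjusted p = 0.00281; over all genes adjusted p = 0.772 with an estimated correlation). Of 44 remodelling enzyme genes 19 rose and 8 fell (19 and 10 adjusted over the list alone), including Pcolce2, an enhancer of procollagen processing (2.98, SE 0.15), and Mmp2 (2.14, SE 0.12), and the list was shifted up (camera adjusted p = 0.0297; adjusted p = 0.668 with an estimated correlation). Of 27 receptor genes 9 rose and 5 fell (the same adjusted over the list alone; camera adjusted p = 0.625).

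**Figure D3:**
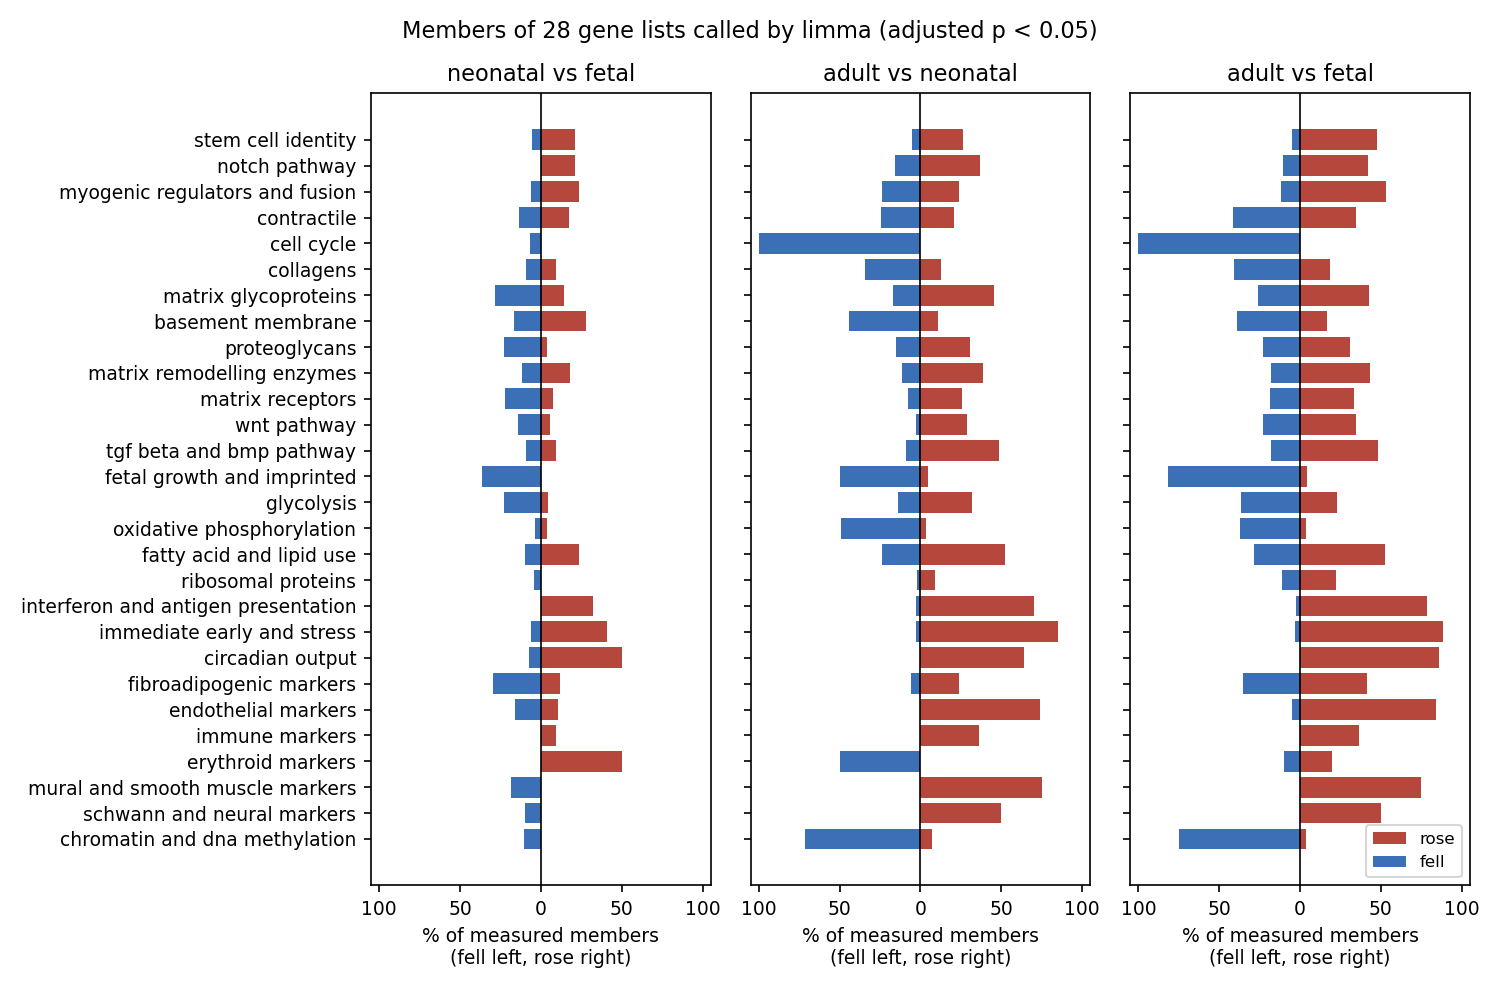
Percent of the measured members of each of the 28 gene lists that fell (left of 0) or rose (right of 0) by limma, in 3 panels for the 3 comparisons. In adult against neonatal cells 45 of 45 cell cycle genes fell, and in adult against fetal cells 29 of 37 interferon and antigen presentation genes and 30 of 34 immediate early and stress genes rose.

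In adult against fetal cells all 45 cell cycle genes fell (45 adjusted over the list alone; median -2.53; camera adjusted p = 3.62e-20; adjusted p = 0.329 with an estimated correlation). In the chromatin list 21 of 28 genes fell and 1 rose (21 and 2 adjusted over the list alone; camera adjusted p = 1.29e-05; adjusted p = 0.226 with an estimated correlation). In the fetal growth and imprinted list 18 of 22 genes fell and 1 rose (the same adjusted over the list alone; median -1.05; camera adjusted p = 2.30e-07; adjusted p = 0.0577 with an estimated correlation). Of 57 oxidative phosphorylation genes 21 fell and 2 rose (20 and 2 adjusted over the list alone; camera adjusted p = 0.00400; adjusted p = 0.647 with an estimated correlation). Of 37 interferon and antigen presentation genes 29 rose and 1 fell (30 and 1 adjusted over the list alone) (camera adjusted p = 1.62e-11; adjusted p = 0.293 with an estimated correlation). H2-D1 rose by 3.94 (SE 0.20). Of 34 immediate early and stress genes 30 rose and 1 fell (32 and 1 adjusted over the list alone) (camera adjusted p = 4.23e-13; adjusted p = 0.282 with an estimated correlation). Atf3 rose by 2.43 (SE 0.14). Of 14 circadian genes 12 rose and 0 fell by limma (13 and 0 adjusted over the list alone) (camera adjusted p = 1.07e-06; adjusted p = 0.274 with an estimated correlation). Nr1d1 rose by 3.51 (SE 0.12). Of 19 stem cell identity genes 9 rose and 1 fell (the same adjusted over the list alone) (camera adjusted p = 0.0175; adjusted p = 0.331 with an estimated correlation). Calcr rose by 2.14 (SE 0.22) and the growth factor receptor gene Fgfr1 by 1.63 (SE 0.21). Of 17 myogenic regulator and fusion genes 9 rose and 2 fell (9 and 3 adjusted over the list alone; camera adjusted p = 0.0969; 0.0409 when genes under the median intensity were left out; over all genes adjusted p = 0.350 with an estimated correlation). Of 29 contractile genes 10 rose and 12 fell (the same adjusted over the list alone; 0.883).

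Markers of other cell types moved apart between fetal and adult cells. Of 19 endothelial markers 16 rose and 1 fell (the same adjusted over the list alone) (camera adjusted p = 1.80e-06; adjusted p = 0.393 with an estimated correlation). The vessel wall gene Vwf rose by 1.95 (SE 0.23), although the list was not called when genes under the median intensity were left out (0.209). Of 16 mural and smooth muscle markers 12 rose and 0 fell by limma (13 and 0 adjusted over the list alone; camera adjusted p = 0.000467; adjusted p = 0.350 with an estimated correlation). Of 10 Schwann and neural markers 5 rose and 0 fell by limma (the same adjusted over the list alone; camera adjusted p = 0.0538), with Sox10 up by 2.84 (SE 0.18), and the list was called without fetal replicate 3 (0.0318), neonatal replicate 1 (0.0256), neonatal replicate 2 (0.0469) or adult replicate 3 (0.0433), and with the mean of all probes of a gene (0.0217). On all arrays it had an adjusted p = 0.350 with an estimated correlation. Of 17 fibroadipogenic markers 7 rose and 6 fell (7 and 7 adjusted over the list alone; camera adjusted p = 0.996): the receptor gene Pdgfra fell by 2.13 (SE 0.30) and Gsn and Dpt rose by 2.67 (SE 0.40) and 1.53 (SE 0.25), and the list's median was -0.22 and its mean 0.11. Of 11 immune markers 4 rose and 0 fell by limma (the same adjusted over the list alone; camera adjusted p = 0.0705), with Cd14 up by 1.70 (SE 0.18). Of 10 erythroid markers 2 rose and 1 fell (the same adjusted over the list alone; camera adjusted p = 0.180), the 2 being the globin genes Hba-a1 (at 9.71 in fetal and 13.71 in adult cells) and Hbb-bt (3.43, SE 0.51).

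**Figure D4:**
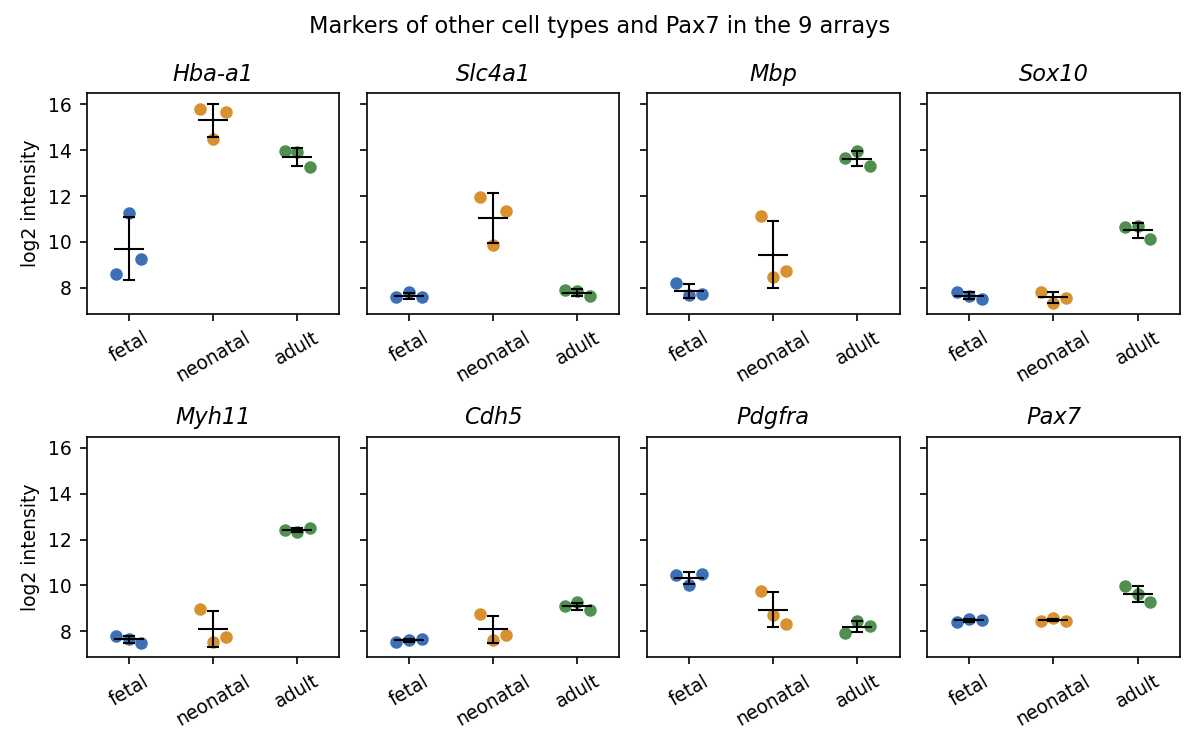
Log2 intensity (y axis) of 7 markers of other cell types and of the stem cell gene Pax7 in fetal, neonatal and adult cells; each point is 1 array and bars give mean ± SD of 3 arrays. Sox10 lies at 7.66 in fetal, 7.58 in neonatal and 10.50 in adult cells, while Pdgfra lies at 10.34, 8.94 and 8.21.

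The last comparison asked how far both steps involved the same genes. Of the genes tested, 850 were called by limma in both, 482 in the same direction and 368 in opposite directions. The same-direction genes comprised 272 that rose in both steps, where independent lists of these sizes would share 143, and 210 that fell in both, where they would share 157. Genes that rose and then fell numbered 170 (141 for independent lists), and genes that fell and then rose numbered 198 (160 for independent lists). Every pair of directions thus exceeded its count for independent lists over all genes tested, the opposite ones included. Those counts treat dim genes like all others, and genes that are hard to call in either step raise every excess. With genes at or above the median intensity alone, 362 were called in the same direction and 220 in opposite directions. Their first step held 532 rises and 489 falls, and their second 1394 and 1676. The excess in opposite directions cannot be taken to hold among them. Among the matrix genes, Col5a1, Col18a1, Tnc, Matn2, Mfap2, Mfap4 and Vcan fell in both steps, Reln, Ccn2 and Prelp rose in both, 4 including Hspg2 and Col15a1 rose and then fell, and 5 including Fbln2 and Ogn fell and then rose. Both steps share the neonatal arrays: in 20 simulations without any effect limma called 0 genes in both steps, and 1.55 genes on average passed in the same direction at an unadjusted p, against 1007 observed. In opposite directions 134 genes on average passed at an unadjusted p, against 785 observed. The correlation of the log2 changes across genes was 0.063, against -0.50 in those simulations, and their covariance was 0.0175 against -0.0128. Those simulations changed no gene and drew the noise of each array independently, without any pairing of neonatal with fetal arrays. They show what the shared arrays add by themselves and cannot show whether the steps involve the same genes. The shared arrays thus add mainly genes of opposite direction, and since the 3 neonatal arrays are too few to be split, part of the opposite-direction count of 368 may come from them. The same-direction count was 262 without fetal replicate 2, 270 without fetal replicate 3, 315 without neonatal replicate 2 and 274 without neonatal replicate 3. The opposite-direction count was 215, 219, 228 and 162 in the same order.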

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

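All 6 tests of the 3 patterns below were chosen after the results were seen; the counts of splits were planned before. Xist was bright in fetal (11.54 ± 0.22) and neonatal (11.71 ± 1.03) arrays and near the low end in adult arrays (7.30 ± 0.18). Loss of Xist with age in sorts of like sex would leave genes of the Y chromosome level, but Eif2s3y, the brightest of 3 measured Y-linked genes and chosen after its values were seen, was higher in adult cells by 1.29 against neonatal cells (SE 0.15, limma adjusted p = 4.66e-05). That value cannot exclude an age-related loss, because these arrays cannot show whether Eif2s3y itself changes with age. A higher share of male cells in the adult sorts stays open as well: Eif2s3y was higher against fetal cells by 1.14 (SE 0.15, limma adjusted p = 6.20e-05), but Kdm5d and Uty, dimmer Y-linked genes also chosen after their values were seen, differed by -0.04 and -0.28 against fetal and by 0.53 (called) and -0.09 against neonatal cells. More male cells would also lower X-linked genes that escape inactivation. Of 4 measured, however, Ddx3x was called higher by 0.51 against fetal cells (limma adjusted p = 0.0227) and by 0.46 against neonatal cells (0.0428). Kdm5c was called higher by 0.42 against neonatal cells (0.0305). Eif2s3x (-0.29 against fetal and -0.37 against neonatal cells) and Kdm6a (0.18 and 0.16) were not called. These explanations cannot be told apart, so sex and age may be mixed in both adult comparisons.

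Of endothelial, mural and Schwann markers 14 of 19, 12 of 16 and 5 of 10 were called higher in adult than in neonatal cells. Against fetal cells 16, 12 and 5 were higher and 1 endothelial marker was lower. The Schwann list was not called against fetal cells (camera adjusted p = 0.0538). No camera call of these lists held with an estimated correlation (camera adjusted p = 0.295 to 0.393). A lower share of stem cells in the adult sorts, as the whole cause, would raise markers of every other type and lower Pax7, but Pax7 was higher in adult than in fetal cells by 1.15 (SE 0.16, limma adjusted p = 0.000104) and than in neonatal cells by 1.13. Of 17 fibroadipogenic markers 7 were higher and 6 lower against fetal cells, and 4 higher and 1 lower against neonatal cells, so a lower share as a part of the cause, with Pax7 rising in the stem cells, stays open. Cells of vessels and nerves carried into the adult sorts may account for the pattern: 31 of 45 members of the 3 lists (68.9%) were called higher against neonatal cells, between the bounds of 20% and 80% set for that test, so this explanation and expression of the same genes by adult stem cells cannot be told apart; a sort on α7-integrin and CD34 admits CD34-positive vessel cells only if they also carry α7-integrin. Neonatal replicate 1 stood apart, with endothelial, mural and Schwann list medians of 8.57, 9.81 and 8.88. These were 7.72, 9.02 and 8.13 in neonatal replicate 2 and 7.86, 8.98 and 8.32 in neonatal replicate 3. In fetal arrays 10 of 16 mural, 4 of 19 endothelial and 3 of 10 Schwann markers already lay at or above the median of all genes. Of the mural markers 3 belong to another list as well, and a biological difference of age was not tested.

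Of 111 matrix genes 23 were lower and 13 higher in neonatal than in fetal cells, with a median of -1.0002 among the lower ones. For fewer cycling cells in the neonatal sorts, the test asked whether the cell cycle list fell about as far. Its median was -0.24 and its lower quartile -0.31. The -1.0002 covers only genes called lower, and the cell cycle values cover the whole list, so that test cannot decide. Whole-list medians were -0.05 for collagens, -0.07 for glycoproteins, 0.07 for basement membrane and -0.11 for proteoglycans. Fewer cycling cells therefore stay open. Fewer fibroblast-like cells in the neonatal sorts stay open as a cause, although the sort admits them only if they carry both α7-integrin and CD34. Of 17 fibroadipogenic markers 5 were lower and 2 higher. Both higher ones, Dpt and Col15a1, belong to a matrix list themselves, as do 5 of the 17 in all. In fetal arrays 10 of the 17 lay at or above the median of all genes. The list had a median of 8.86 and 8.89 in neonatal replicates 2 and 3 against 10.04 to 10.51 in fetal arrays, but 10.36 in neonatal replicate 1, without which it was called lower (adjusted p = 0.00109; on all arrays adjusted p = 0.219, and 0.772 with an estimated correlation). A change of matrix expression with age in the stem cells themselves stays open and was not tested.

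The 6 arrays of each comparison can be split in 10 ways, too few for a share under 0.05. For neonatal against fetal cells 1 of the 10 splits, the real one, gave as many as 1590 genes, and the highest of the others gave 0 by limma (797 at an unadjusted p). For adult against neonatal cells 1 of 10 gave as many as 4718, and the highest of the others 0 (1395 at an unadjusted p), and for adult against fetal cells 1 of 10 gave as many as 5654, and the highest of the others 0 (747 at an unadjusted p). Replicate numbers were taken to pair the neonatal and fetal arrays, which the check does not establish. Among the 4 splits that part all such pairs the highest of the others also gave 0. The splits that part fewer pairs put arrays of the same number on one side. For the overlap of the steps, 1 of 100 drawn splits of the 9 arrays gave as many as 482 genes, the highest of the others giving 0. These other splits mix ages within groups, which widens the spread that limma estimates, and they do not keep the pairs of neonatal and fetal arrays. Chance can therefore be excluded only against such mixed groups, not against smaller departures from the real one. For the number of list calls, 32 of 100 drawn splits gave 32 or more and the highest of the others gave 42, so chance cannot be excluded for that number. The same mixing of ages applies there.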

How the results depend on the processing

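Background correction and leaving out both first replicates were chosen after seeing the data; all other alternatives were planned. Without both first replicates of fetal and neonatal cells, 1469, 4646 and 5485 genes were called for neonatal against fetal, adult against neonatal and adult against fetal cells. In that setting 430 genes were called in the same direction in both steps, and camera called 41 of the 84 list tests. With genes at or above the median intensity alone, 1021, 3070 and 3525 were called, from fewer genes tested. With all probes tested one by one, 8092 and 9926 probes were called at the second step and over the whole interval, 2543 at the first, and 737 in the same direction in both, from more features. With a log2 change of at least 1 the calls were 389, 1306 and 1812, and at an adjusted p under 0.01 they were 745 for the first step and 3057 for the second. Array weights gave 2833 calls for the first step and an overlap of 797, and 4079 genes did not overlap between fetal and neonatal arrays, where chance gives 10%; the cause of these was not tested. Leaving out each array in turn gave 881 to 1831, 3556 to 5027 and 4660 to 5810 genes, an overlap of 262 to 536 and 32 to 41 list calls, from fewer samples. With the correlation estimated for each list camera called 0 of 84 list tests (13 at an unadjusted p), against 32 with the preset correlation and 45 by fry. Fry asks whether a list changed at all, camera whether it changed more than other genes, so these counts differ in kind. Fry ended the cell cycle call of the first step and added calls. These were Notch and glycolysis at the first step and Notch, glycolysis, stem cell identity, matrix receptor, lipid use and immune lists at the second. Between fetal and adult cells they were Notch, myogenic, TGF-beta, lipid use, immune and Schwann lists. The endothelial list of neonatal against fetal cells turned from a median of 0.09 to -0.78 with genes at or above the median intensity; the alternative leaves out its dim members. With the replicate number as a block 1846, 4930 and 5862 genes were called, 581 in the same direction in both steps, and camera called 34 of the 84 list tests. The block added the oxidative phosphorylation list of the first step (camera adjusted p = 0.0378) and the glycoprotein list of the second (0.0261). Without the block these have camera adjusted p = 0.739 and 0.668 with an estimated correlation. The block ended 2 calls of named genes and added 5. By the bound of the check the numbers were taken to pair neonatal with fetal arrays. For adult arrays same-numbered deviations correlated at -0.028 to 0.244 with neonatal and -0.059 to 0.149 with fetal arrays.

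Of 365 calls of named genes 95 were lost under at least 1 alternative and 0 reversed in limma fits. The filters at the 25th percentile and at the median tested only 352 and 253 of these calls, so the remaining 270 were not all tested under every alternative; a log2 change of at least 1 ended 90, an adjusted p under 0.01 ended 36 and leaving out neonatal replicate 3 ended 30. Floors of 4 and 64 lay below the lowest intensity of 118 and could change nothing. No scaling moved the share of rises by over 10 percentage points: with cyclic loess it was 49.7%, 56.1% and 53.7%, against 47.2%, 50.4% and 48.3%. The intensities carry background, which compresses the changes of dim genes. Normexp correction raised the median size of called changes from 0.70, 0.70 and 0.75 to 0.94, 0.95 and 1.03, with every sign kept. Subtracting background enlarges log2 changes by itself, and these medians cover all called genes, so the rise does not measure that compression. Under normexp limma called 1231, 4396 and 5493 genes, 344 in the same direction in both steps, and 16 calls of named genes were lost.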

Other observations

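No test in this part was chosen after its result was seen. Of 33 genes of the TGF-beta and BMP pathway 3 rose and 3 fell between fetal and neonatal cells (3 and 5 adjusted over the list alone; camera adjusted p = 0.284). Between neonatal and adult cells 16 rose and 3 fell (the same adjusted over the list alone; camera adjusted p = 0.00369; adjusted p = 0.274 with an estimated correlation), with the ligand gene Bmp6 up by 2.35 (SE 0.17) and the co-receptor gene Tgfbr3 by 2.56 (SE 0.22). Between fetal and adult cells 16 rose and 6 fell (16 and 9 adjusted over the list alone; camera adjusted p = 0.0554), with Bmp4 up by 2.01 (SE 0.15) and the BMP antagonist gene Nog down by a change of -1.29 (SE 0.11), and the list was called without fetal replicate 1 (0.0440) or adult replicate 1 (0.0355) and when genes under the median intensity were left out (0.0394). On all arrays and genes it had an adjusted p = 0.340 with an estimated correlation. Of 35 Wnt pathway genes 2 rose and 5 fell at the first step, 10 rose and 1 fell at the second, and 12 rose and 8 fell between fetal and adult cells, with the same counts adjusted over the list alone each time (camera adjusted p = 0.661, 0.318 and 0.625). The secreted Wnt antagonist genes Sfrp2 and Sfrp5 went opposite ways between fetal and adult cells, Sfrp2 falling by a change of -2.62 (SE 0.12) and Sfrp5 rising by 2.97 (SE 0.34). Of 19 Notch pathway genes 4 rose and 0 fell by limma at the first step (5 and 0 adjusted over the list alone; camera adjusted p = 0.103), including the ligand gene Dll1 (1.56, SE 0.31), and this list was called without neonatal replicate 1 (0.0412) and when genes under the median intensity were left out (0.0218; over all arrays and genes adjusted p = 0.422 with an estimated correlation). At the second step 7 rose and 3 fell (8 and 3 adjusted over the list alone; 0.244), and between fetal and adult cells 8 rose and 2 fell (the same adjusted over the list alone; 0.0715), including the Notch target gene Hey1 (1.03, SE 0.11). Between fetal and adult cells the Notch list was called when genes under the median intensity were left out (0.00717; over all genes adjusted p = 0.373 with an estimated correlation).

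Metabolic lists held members that moved in opposite directions. Of 22 glycolysis genes 1 rose and 5 fell between fetal and neonatal cells (2 and 5 adjusted over the list alone; camera adjusted p = 0.101), 7 rose and 3 fell between neonatal and adult cells (the same adjusted over the list alone; 0.273), and 5 rose and 8 fell between fetal and adult cells (the same adjusted over the list alone; 0.940, with a median of 0.07 while the test pointed down). The isoenzyme genes of phosphofructokinase separated between fetal and adult cells: the platelet form Pfkp rose by 2.49 (SE 0.16) and the liver form Pfkl fell by 1.34 (SE 0.12). Of 21 genes of fatty acid and lipid use 5 rose and 2 fell at the first step (5 and 3 adjusted over the list alone; 0.149, and 0.0190 when genes under the median intensity were left out; over all genes adjusted p = 0.451 with an estimated correlation), 11 rose and 5 fell at the second (the same adjusted over the list alone; 0.180), and 11 rose and 6 fell between fetal and adult cells (the same adjusted over the list alone; 0.107). Pdk4, a kinase that restrains glucose oxidation, and the triglyceride lipase gene Pnpla2 rose between fetal and adult cells by 2.24 (SE 0.14) and 2.12 (SE 0.24), and the fatty acid carrier gene Fabp5 fell by 2.16 (SE 0.15). Of 57 oxidative phosphorylation genes 2 rose and 2 fell between fetal and neonatal cells (2 and 0 adjusted over the list alone; camera adjusted p = 0.0538). That list was called higher in neonatal cells with the replicate number as a block (0.0378) and without fetal replicate 2 (0.0443), fetal replicate 3 (0.0127), neonatal replicate 1 (0.00545) or adult replicate 3 (0.0454), and with the mean of all probes of a gene (0.0459). On all arrays it had an adjusted p = 0.739 with an estimated correlation. Of 45 ribosomal protein genes 0 rose and 2, Rpl4 and Rplp0, fell by limma at the first step (the same adjusted over the list alone; 0.233), 4 rose and 1 fell at the second (0 and 0 adjusted over the list alone; 0.362), and 10 rose and 5 fell between fetal and adult cells (6 and 4 adjusted over the list alone; 0.996, with a median of 0.003 and a mean of -0.03).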
